A study of Mus musculus with 8 samples.

How the data were processed

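Gene expression was measured by RNA-seq in 4 libraries of mouse induced cardiomyocytes on day 5, 2 labelled shNT and 2 labelled shGrhl3, all from cells treated with MGT per the labels. The series also lists 4 H3K27ac CUT&Tag samples, which were not analysed here. The authors deposited a single table of raw counts per gene, with a column for each RNA-seq library. Its values are whole numbers with different totals per library, and no normalization was found in them. Per the submitters' processing notes, the series used cutadapt 1.9.1, HISAT2 2.0.1, Bowtie2 2.2.6, MACS2 and ChIPseeker with the mm10 genome. Those notes do not say which tool served which assay. The program that counted reads per gene, the annotation, the strand setting and the treatment of reads that fit several places are not given in the sources used here. Reads of paralogs, pseudogene families and antisense partners can therefore be split, dropped or merged in these counts. Gapdh, for example, had only 126 to 160 counts per library.

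The hairpin columns are named shGrhl1 and shGrhl2, names that could also be read as hairpins against Grhl1 and Grhl2. They were matched to the shGrhl3 titles because Grhl3 is the only target the labels name, with the digit read as the replicate number of the title. The table has 55359 rows, of which 1438 name no gene. These rows held between 0.00432% and 0.00872% of the counts of a library and were left out of library sizes and tests. A further 1705 rows share a symbol with another row and were kept as separate rows in the main analysis. Of 52324 distinct symbols, 49940 were found in a gene name table. Gene positions are those of RefSeq genes on GRCm38.p6, the assembly behind mm10, as start and end of the whole gene.

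Before averaging, the libraries of each group were compared. The chi-square statistic per degree of freedom of their counts was 14.1 for the shNT pair and 8.66 for the shGrhl3 pair, above sampling noise, and 52.4 to 67.1 between groups. Pearson's correlation of log2 CPM across genes was 0.989 and 0.988 within groups and 0.963 to 0.967 between groups, where genes are not independent replicates. No library looked like a second deposit of another.

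Differential expression was tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered by filterByExpr at its default minimum count of 10, which left 15324 genes. Library sizes were scaled by TMM factors, and a quasi-likelihood model with robust spread estimates was fitted to the shNT and shGrhl3 groups with no covariate. Tests are two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and the threshold was 0.05. Fold changes are shGrhl3 against shNT. CPM values use the TMM-scaled library sizes, and ± gives the SD over the 2 libraries of a group. The SE of a log2 fold change was derived from the quasi-likelihood F statistic. The depth sets the precision: at these totals, a gene with 10 counts has a CPM near the level of Grhl3, where counting error is large.

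Before the data were examined, 29 gene lists with 894 entries were written from textbook knowledge, of which 893 entries were found in the table. They cover cardiomyocyte programs, the reprogramming factors, matrix genes, fibroblast and myofibroblast genes, Hippo-YAP targets, epithelial genes, cell cycle, interferon, inflammation, energy metabolism, p53, unfolded protein response, Wnt, Notch and markers of 7 other cell types. The 27 lists with at least 5 tested members were tested with camera (limma 3.58.1, preset correlation 0.01) on log2 CPM, adjusted over the 27 lists. Camera with an estimated correlation and the rotation test fry were run beside it. With the preset correlation 15 lists passed, with an estimated correlation 0 passed (lowest adjusted p = 0.419), and with fry 17 passed. The estimated correlation rests on the residuals of only 4 libraries, which also leave that test few degrees of freedom. Lists with an estimated correlation below the preset 0.01 lost the threshold too. The p53 targets, at -0.013, went from an unadjusted camera p of 0.00388 to 0.0858. A loss under this test therefore does not show that correlated genes produced the preset result. Fry asks whether a list moves one way, not whether it differs from other genes.

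The genes named in the text follow a rule also set in advance. It takes Grhl1, Grhl2, Grhl3, Mef2c, Gata4 and Tbx5, and the 10 highest and 10 lowest fold changes among genes past the threshold with at least 4 on the log2 CPM scale and no overlap between groups, leaving out predicted genes. It adds up to 4 members per list with the lowest p past the threshold, and the 5 lowest p-values in each direction. Some genes that the rule takes or a count includes are not reported here by name. Genes outside it are said to be chosen after their values were seen or named because a count is small. The rising collagens, Csf1r, Lyz2 on its list, Ccnd1 and the rRNA-related genes are also of that kind.

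The test was tried on simulated counts drawn from the means and library sizes of these libraries (15324 genes, 200 of them changed). It recovered 52.2% of genes changed 1.5-fold, 76.1% of those changed 2-fold and 93.9% of those changed 4-fold. Of 158 calls, 10 (6.33%) were false, and with no gene changed there were 0 calls. Of random unchanged lists, 3.5% had a camera p under 0.05. Genes were drawn independently, so that share holds for uncorrelated genes only, whereas the interferon list had an estimated correlation of 0.719. Only 200 genes were changed, against 5402 called in the data, so the recovery and false-call shares may differ there.

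Alternatives set in advance were other scaling factors (RLE, upper quartile, library size only), DESeq2 1.42.0, limma-voom, edgeR's legacy fit, no expression filter, a stricter filter (CPM of at least 1 in every library of a group), a replicate block, each library left out in turn, a fold change minimum, an adjusted p of 0.01, an estimated list correlation, fry, and lists without shared genes. Alternatives chosen after seeing the data left out the rRNA-related rows (Rn18s, Lars2 and the small rRNA genes), summed rows that share a symbol, and crossed the replicate numbers. Checks of GC content need a genome sequence and were not run.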

Results

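The series measured gene expression in mouse induced cardiomyocytes, which are fibroblasts driven towards a heart muscle cell identity by forced expression of transcription factors. All cells received the factor mix labelled MGT, which in this field stands for Mef2c, Gata4 and Tbx5, and were collected on day 5. Cells carried either a short hairpin RNA against Grhl3, a Grainyhead-like transcription factor best known from epithelial development, or the hairpin labelled shNT, taken here as the control. RNA-seq counts were read for 2 shNT and 2 shGrhl3 libraries. Counts totalled 19257692 and 16104243 in the shNT libraries, and 19823397 and 18609743 in the shGrhl3 libraries. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The H3K27ac CUT&Tag samples were not analysed here. The question set by the series title is how Grhl3 affects the extracellular matrix and the conversion of fibroblasts into cardiomyocytes.

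Grhl3 itself (chromosome 4, 135541887 to 135573632, mm10) had low counts in all 4 libraries. It had 31 and 14 counts in the shNT libraries and 11 and 19 in the shGrhl3 libraries. Its mean level was 1.25 ± 0.522 CPM (counts scaled by TMM-adjusted library size; SD, n = 2) in shNT and 0.783 ± 0.331 CPM (SD, n = 2) in shGrhl3, with overlapping libraries. The log2 fold change was -0.72 (SE 0.53, 95% interval -1.81 to 0.37), with an adjusted p of 0.311 in edgeR's quasi-likelihood test. A fall in Grhl3 mRNA was therefore not detected. The interval reaches from a fall of 1.81 on the log2 scale to a rise, so the counts neither bear out nor contradict the labels. The table columns read as the shGrhl3 libraries are named shGrhl1 and shGrhl2. These names could also be read as hairpins against Grhl1 and Grhl2, but the labels name only Grhl3 as a target, so the digit was taken as the replicate number. Of the related family members, Grhl1 stood at 0.434 ± 0.347 CPM in shNT and 1.29 ± 0.00846 CPM in shGrhl3 (SD, n = 2; log2 fold change 1.49, SE 0.59, adjusted p = 0.0549). Grhl1 passed with scaling by library size only (adjusted p = 0.0493), the stricter filter (0.0408) and the crossed replicate block (0.0486). It passed under no other alternative fitted to all 4 libraries. Its log2 fold change was 2.73 without shNT replicate 1 and 0.92 without shNT replicate 2. Grhl2 had 0 and 5 counts in shNT, 1 and 0 in shGrhl3, and was too low to test.

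The mRNAs of the delivered factors were abundant in every library. Tbx5 fell from 915 ± 40.9 to 739 ± 9.93 CPM (log2 fold change -0.31, SE 0.08, adjusted p = 0.00311). Gata4 fell from 584 ± 9.28 to 499 ± 39.4 CPM (log2 fold change -0.23, SE 0.08, adjusted p = 0.0320). Mef2c stood at 396 ± 32.1 CPM in shNT and 306 ± 81.1 CPM in shGrhl3, a difference that did not pass the test (log2 fold change -0.37, SE 0.18, adjusted p = 0.189). The reprogramming factor list thus had 2 of 3 members lower and 0 higher, and the counts were the same when adjusted over the list alone. Reads from delivered and native copies share these rows and were not separated. The Tbx5 call was lost without shNT replicate 1, where its log2 fold change was -0.26. The Gata4 call was lost with scaling by library size only (adjusted p = 0.0582). It was also lost without each of shNT replicate 1, shNT replicate 2 and shGrhl3 replicate 1. Fits with a library left out pooled the spread over nearly all genes, so calls there carry little of each gene's own spread. Mef2c passed as lower with limma-voom (adjusted p = 0.0116), and its adjusted p reached 0.427 over all alternatives. Its log2 fold change was -0.65 without shGrhl3 replicate 2 and -0.12 without shGrhl3 replicate 1, and that of Gata4 was -0.15 without shGrhl3 replicate 1.

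Expression differed widely between the arms. Of 15324 genes tested, 5402 (35.3%) passed an adjusted p of 0.05, with 2632 higher and 2770 lower in shGrhl3 cells. At least a 2-fold difference was seen in 512 of the higher and 656 of the lower genes. Among the highest fold changes of well expressed genes, Tnnt3, a fast skeletal troponin T, rose 16.8-fold, and Myh6, the alpha myosin heavy chain of heart muscle (chromosome 14, 54941921 to 54968017), rose 12.2-fold. Mb, encoding the oxygen store myoglobin, rose 8.40-fold, and Mmp15, a membrane-bound matrix metalloproteinase (chromosome 8, 95352296 to 95374293), rose 8.01-fold. The same rule also named Wnt5b, Tnni3, Trib3, Epha4 and Adprhl1, which rose between 4.87-fold and 6.16-fold. Among the lowest, Cd36, a fatty acid and lipoprotein receptor (chromosome 5, 17781690 to 17888959), fell from 72.4 ± 17.8 to 2.03 ± 0.519 CPM (SD, n = 2). Mpeg1, Ctss, Lyz2 and Cd68, typical macrophage genes, had log2 fold changes of -3.24, -3.23, -2.63 and -2.46. Eif5a2, Tnfsf9, Apoe, Iigp1 and Gpm6b followed, with log2 fold changes between -2.01 and -1.83. The Iigp1 call (adjusted p = 0.0295) was lost with no expression filter (0.0879), and its adjusted p reached 0.197 over all alternatives. The lowest p-values among falling genes, after Ctss, were those of Fhl2, a LIM-domain gene of heart and fibroblasts (838 ± 25.8 to 241 ± 10.3 CPM), Vps35 (331 ± 9.56 to 113 ± 2.08 CPM), Arl2bp (94.3 ± 1.78 to 26.7 ± 3.23 CPM) and Sgpl1 (265 ± 0.407 to 101 ± 2.01 CPM).

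The shares of several RNA classes were also compared between the libraries. The small-subunit rRNA gene Rn18s took 0.573% (95% Wilson interval 0.569 to 0.576) and 2.00% (1.99 to 2.01) of counts in the shNT libraries. Its shares were 0.0959% (0.0945 to 0.0973) and 0.156% (0.154 to 0.157) in the shGrhl3 libraries. These intervals cover counting error only, and the group difference did not pass the test (log2 fold change -3.38, SE 0.99, adjusted p = 0.139). The summed CPM of the leukocyte marker list was 810 ± 181 in shNT and 142 ± 22.3 in shGrhl3 (SD, n = 2). Lyz2 alone made up 550 ± 135 CPM of the shNT sum and 88.6 ± 18.2 CPM of the shGrhl3 sum. Mitochondrially encoded genes took 2.16 ± 0.0607% of counts in shNT and 2.51 ± 0.0223% in shGrhl3, while ribosomal protein genes took 2.06 ± 0.0477% and 2.06 ± 0.117% (SD, n = 2). With the rRNA-related rows left out, an alternative chosen after these shares were seen, 5453 genes passed.

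**Figure D1:**
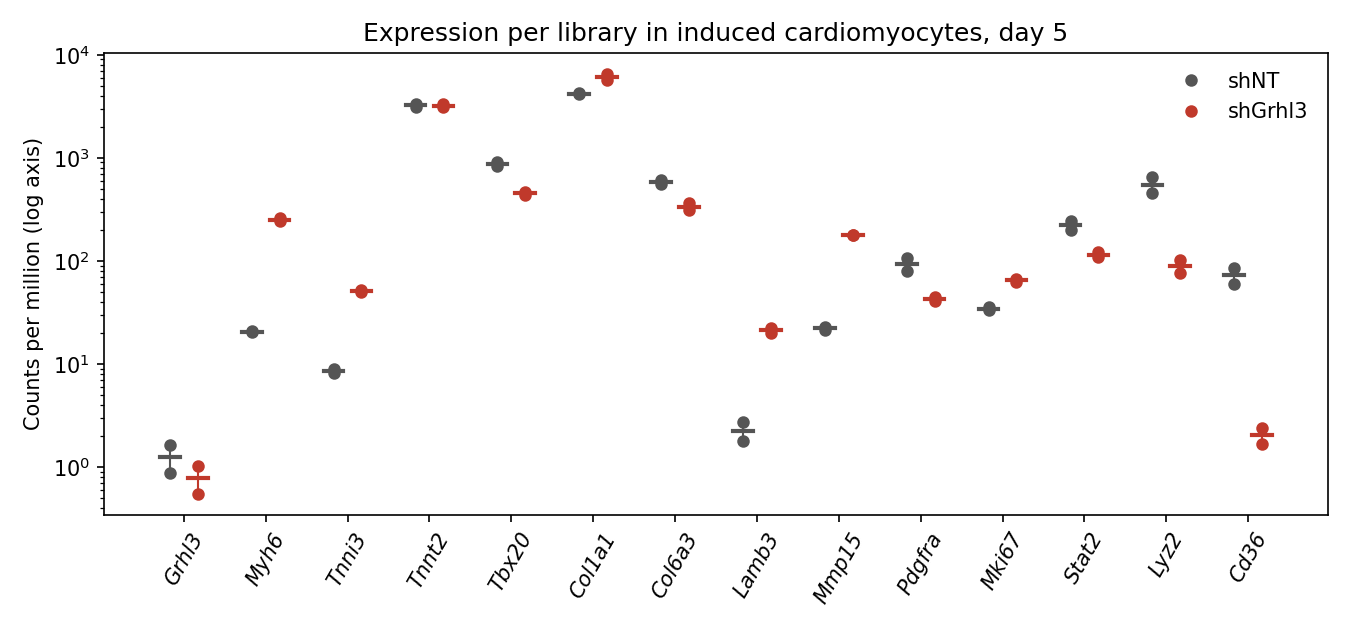
CPM on a log axis for 14 genes in the 2 shNT libraries (grey) and the 2 shGrhl3 libraries (red); points are libraries and horizontal bars are group means (n = 2). Myh6 lies near 20.6 CPM in shNT and 251 CPM in shGrhl3, Cd36 at 72.4 and 2.03 CPM, and Grhl3 overlaps between the groups. Tnnt2, Col1a1 and Mki67 were added to the plot after their values were seen.

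Contractile genes of the heart that passed were mostly higher in shGrhl3 cells. Of 27 tested sarcomere and contractile genes, 15 rose, 3 fell and 9 did not pass (16 and 4 when adjusted over the list alone), with a median log2 fold change of 0.45. Myh6 rose from 20.6 ± 0.284 to 251 ± 14.0 CPM (SD, n = 2; log2 fold change 3.61, SE 0.10, adjusted p = 1.54e-17). Tnni3, the cardiac troponin I, rose from 8.49 ± 0.551 to 50.9 ± 0.974 CPM, Csrp3 from 104 ± 3.83 to 241 ± 11.1 CPM and Mybpc3 from 126 ± 9.33 to 273 ± 16.4 CPM. The 3 falling members, named because they are few, were Myl4, the atrial essential light chain (log2 fold change -0.33), Tcap (-0.93) and Pdlim5 (-0.32). Tnnt2, an early marker of the induced state chosen after its values were seen, stood at 3214 ± 112 and 3208 ± 146 CPM (log2 fold change 0.00, SE 0.07, adjusted p = 0.982). As a set the list stood above other genes (camera, preset correlation, adjusted p = 0.000268), which was lost with an estimated correlation (adjusted p = 0.419). Myh6 and Myh7 are near-identical paralogs, and how reads that fit both were counted is not given in the sources used here.

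Genes of calcium handling, ion channels and cell coupling moved in both directions. Of 25 tested members, 10 rose, 3 fell and 12 did not pass (12 and 3 when adjusted over the list alone), with a median log2 fold change of 0.36. Atp2a2, the calcium pump of the sarcoplasmic reticulum, rose from 1111 ± 44.3 to 1884 ± 164 CPM, and Gja1, which encodes the gap junction protein connexin 43, from 127 ± 6.54 to 201 ± 1.88 CPM. The falling members included Kcnj5, a subunit of the atrial potassium channel (430 ± 9.65 to 250.1 ± 0.533 CPM), and Hcn4, a pacemaker channel gene at low counts (log2 fold change -2.15, SE 0.57, adjusted p = 0.00484). The set passed the camera test (adjusted p = 0.0285) but not with an estimated correlation (adjusted p = 0.419). It also missed the threshold under the stricter expression filter (0.0691) and without each of shNT replicate 1, shGrhl3 replicate 1 and shGrhl3 replicate 2 (0.0527 to 0.0684).

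Cardiac transcription factors and natriuretic peptides did not follow the contractile genes as a set. Of 15 tested, 3 rose, 5 fell and 7 did not pass, the same when adjusted over the list alone. Tbx20, a regulator of heart development, fell from 872 ± 51.3 to 454 ± 21.6 CPM (log2 fold change -0.94, SE 0.08, adjusted p = 3.58e-09). Mef2a fell from 248 ± 0.410 to 179 ± 5.66 CPM and Gata6 from 103 ± 3.10 to 76.8 ± 2.66 CPM. Esrrg, a nuclear receptor of oxidative metabolism, rose from 6.41 ± 0.197 to 11.5 ± 0.0296 CPM. The remaining calls, named because they are few, were Ppargc1a and Smyd1, which rose, and Hand2 and Nppa, which fell. The list's median log2 fold change was -0.08 and its mean 0.09, and the list did not stand apart from other genes (camera adjusted p = 0.796), although fry gave an adjusted p of 0.0266.

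Genes of skeletal muscle were mostly higher as well. Of 11 tested, 7 rose, 0 fell and 4 did not pass, the same when adjusted over the list alone, with a median log2 fold change of 1.23. Tnnt3 rose from 3.46 ± 0.536 to 57.6 ± 3.25 CPM. Acta1, the skeletal alpha actin that fetal hearts also express, rose from 2.59 ± 0.992 to 15.1 ± 0.342 CPM, and Myl1 from 2.73 ± 1.13 to 7.06 ± 1.73 CPM. Myh1 rose from 32.0 ± 0.845 to 54.4 ± 0.819 CPM. The set passed the camera test (adjusted p = 0.00970) but not with an estimated correlation (adjusted p = 0.419).

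**Figure D2:**
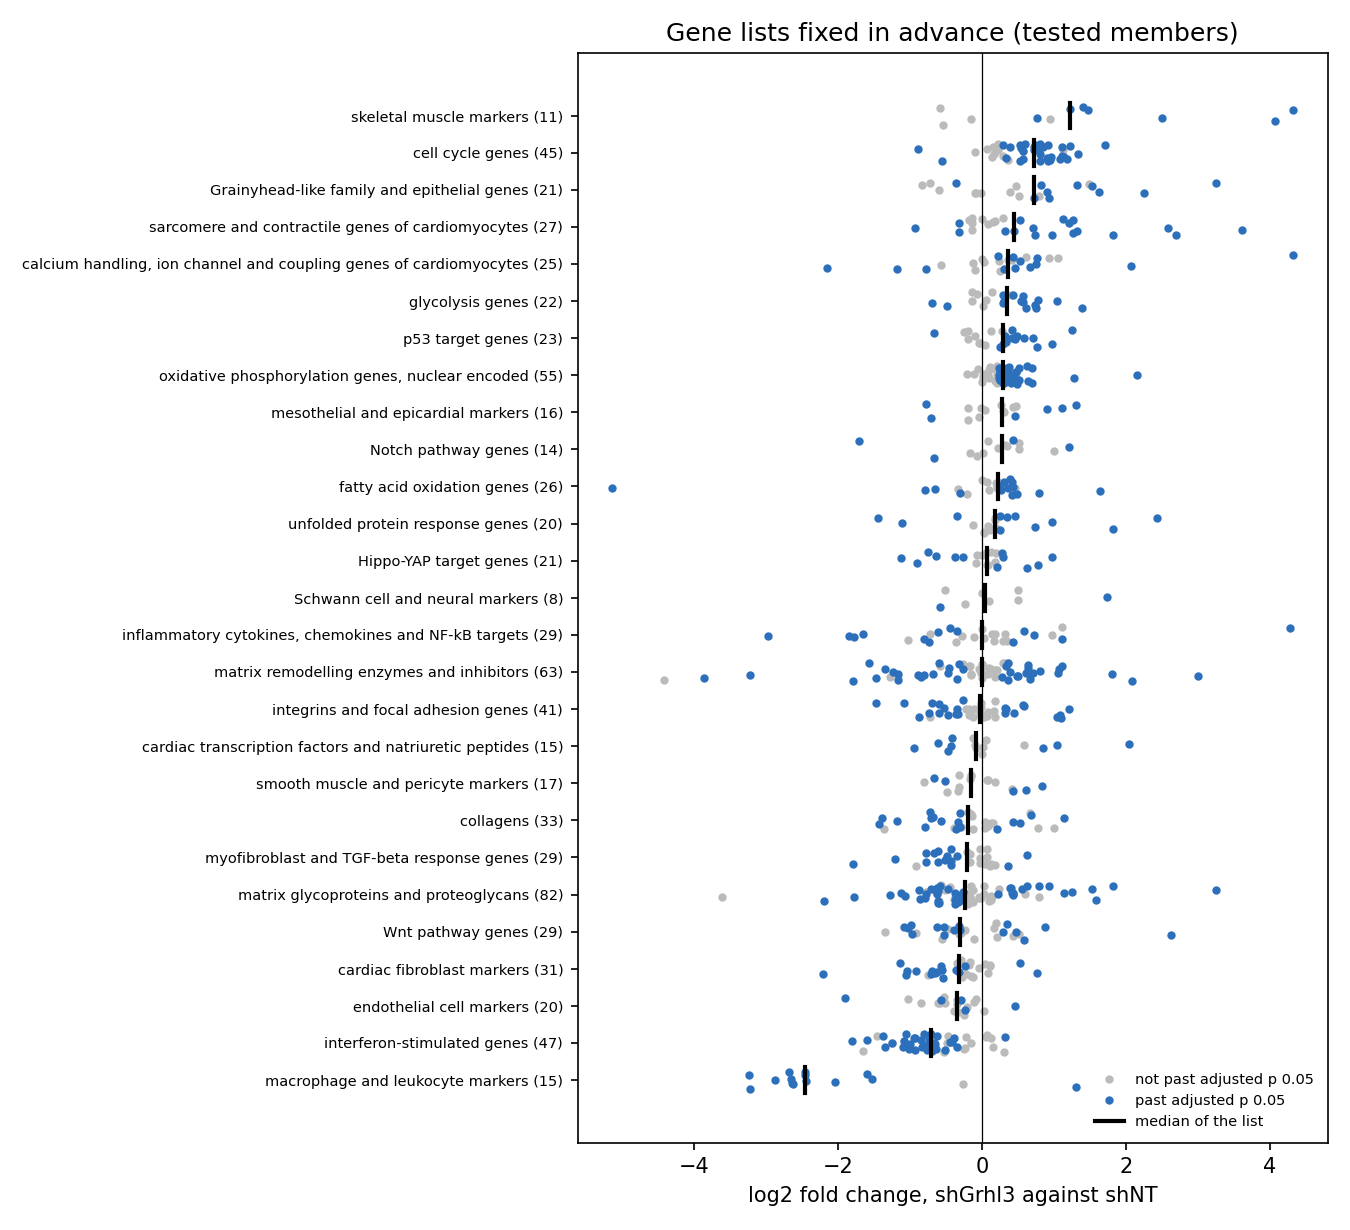
Log2 fold change (shGrhl3 against shNT) of each tested member of the 27 gene lists with at least 5 tested members, with the number of members in parentheses; blue points passed an adjusted p of 0.05, grey points did not, and black bars are list medians. Cell cycle genes have a median of 0.72 and leukocyte markers one of -2.46.

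The extracellular matrix, which the series title names, changed gene by gene. Of 33 tested collagen genes, 5 rose, 12 fell and 16 did not pass, the same when adjusted over the list alone, with a median log2 fold change of -0.19. Col6a3 fell from 584 ± 35.2 to 336 ± 34.97 CPM (log2 fold change -0.80, SE 0.09, adjusted p = 1.36e-07). Col8a1 fell from 721 ± 5.53 to 442 ± 19.5 CPM, and Col7a1, which anchors epithelia to their matrix, from 25.04 ± 1.27 to 9.25 ± 0.888 CPM. Col4a4, a basement membrane chain, rose from 109.8 ± 0.738 to 241 ± 35.8 CPM. The other risers were Col4a3, Col12a1, Col5a2 and the main fibrillar chain Col1a1 (4201 ± 58.5 to 6083 ± 588 CPM). The collagens did not stand apart from other genes as a set (camera adjusted p = 0.156), although the rotation test fry, which asks whether the members move one way on balance, gave an adjusted p of 0.0382.

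Matrix glycoproteins and proteoglycans were mixed as well. Of 82 tested, 17 rose, 31 fell and 34 did not pass (18 and 34 when adjusted over the list alone), with a median log2 fold change of -0.23. Aspn, a small leucine-rich proteoglycan, fell from 42.6 ± 0.694 to 12.5 ± 0.363 CPM. Lamb3, the beta chain of the epithelial laminin-332, rose from 2.24 ± 0.658 to 21.1 ± 1.46 CPM (log2 fold change 3.26, SE 0.21, adjusted p = 5.47e-11). Spon2 rose from 22.7 ± 0.446 to 65.4 ± 0.125 CPM and Podn from 60.4 ± 3.28 to 134 ± 16.8 CPM. The set missed the threshold (camera adjusted p = 0.0745) and passed it with DESeq2-transformed values (0.0230), with voom weights (0.0268) and without shNT replicate 1 (0.0383), within a range of 0.0230 to 0.553 over all alternatives.

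Enzymes that remodel the matrix were split evenly. Of 63 tested, 19 rose, 19 fell and 25 did not pass (19 and 22 when adjusted over the list alone). Mmp15 rose from 22.1 ± 0.926 to 178 ± 1.89 CPM (log2 fold change 3.00, SE 0.10, adjusted p = 4.15e-16), and Tgm2, a crosslinking transglutaminase, from 53.8 ± 1.61 to 188 ± 3.63 CPM. Adam10, a membrane sheddase, fell from 320 ± 9.03 to 143 ± 5.38 CPM. Ctss, a lysosomal protease that is also on the leukocyte list, fell from 94.7 ± 13.1 to 10.1 ± 1.14 CPM, beside the lower leukocyte markers of these libraries. The set did not stand apart (camera adjusted p = 0.799). Of 41 integrin and focal adhesion genes, 10 rose and 13 fell, the same when adjusted over the list alone (camera adjusted p = 0.796). Itga8 fell from 159 ± 9.85 to 75.05 ± 2.80 CPM and Itgb8 from 31.0 ± 3.11 to 11.2 ± 1.73 CPM. Cav1, the main protein of caveolae, rose from 41.9 ± 2.81 to 89.9 ± 2.02 CPM, and Sdc1, a heparan sulfate proteoglycan, from 29.3 ± 0.947 to 60.5 ± 0.0778 CPM.

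Cardiac fibroblast markers that passed were mostly lower. Of 31 tested cardiac fibroblast markers, 2 rose, 15 fell and 14 did not pass, the same when adjusted over the list alone, with a median log2 fold change of -0.32. Pdgfra, a receptor that marks cardiac fibroblasts, fell from 93.5 ± 19.4 to 42.3 ± 2.74 CPM (log2 fold change -1.14, SE 0.12, adjusted p = 1.00e-06). Cd34 fell from 25.1 ± 0.650 to 12.1 ± 0.308 CPM, Tcf21 from 300.3 ± 18.9 to 184 ± 24.5 CPM and Fstl1 from 2089 ± 4.76 to 1429 ± 62.1 CPM. The set stood below other genes (camera adjusted p = 0.00325), lost with an estimated correlation (adjusted p = 0.419).

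Of 29 tested myofibroblast and TGF-beta response genes, 2 rose, 13 fell and 14 did not pass (2 and 14 when adjusted over the list alone). Myl9, a regulatory light chain of smooth muscle and contractile fibroblasts, fell from 414 ± 0.258 to 179 ± 22.7 CPM. Tgfbr2 fell from 209.8 ± 20.0 to 122 ± 4.55 CPM and Tpm2 from 375 ± 8.07 to 247 ± 10.8 CPM, whereas the ligand gene Tgfb2 rose from 302 ± 19.0 to 466 ± 17.7 CPM. The camera adjusted p was 0.0171, against an adjusted p of 0.419 with an estimated correlation and 0.0670 without shGrhl3 replicate 2. Targets of Hippo-YAP signalling had 6 of 21 tested members higher and 6 lower, the same when adjusted over the list alone. Rbms3 (87.1 ± 2.13 to 46.7 ± 1.57 CPM) and Lats2 (159 ± 2.11 to 94.6 ± 4.36 CPM) fell, and Nuak2 rose (12.9 ± 1.58 to 25.2 ± 1.15 CPM). The list's median was 0.07 and its mean -0.02 (camera adjusted p = 0.796).

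Several epithelial genes were higher in shGrhl3 cells. Of 21 tested members of the list of epithelial genes and the Grainyhead-like family, 9 rose, 1 fell and 11, Grhl1 and Grhl3 among them, did not pass (10 and 1 when adjusted over the list alone), with a median log2 fold change of 0.72. Besides Lamb3, Krt7 rose from 2.97 ± 0.794 to 13.9 ± 1.97 CPM and St14, which encodes the protease matriptase, from 4.29 ± 0.605 to 12.3 ± 0.358 CPM. Dsp, a desmosome gene of epithelia and also of cardiomyocytes, rose from 425 ± 26.1 to 698 ± 99.0 CPM. The single falling member was Lmo4. The set's camera adjusted p of 0.0205 was lost with an estimated correlation (adjusted p = 0.419), without shGrhl3 replicate 1 (0.0731) and when genes held by several lists were left out (0.131).

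Genes of the cell cycle were mostly higher. Of 45 tested, 31 rose, 2 fell and 12 did not pass (35 and 2 when adjusted over the list alone), with a median log2 fold change of 0.72. Bub1, a mitotic checkpoint kinase, rose from 6.97 ± 0.835 to 22.7 ± 1.03 CPM, Cdc20 from 18.3 ± 3.10 to 46.1 ± 3.44 CPM and Rrm2 from 17.6 ± 1.95 to 39.8 ± 0.858 CPM. The falling members were both D-type cyclins, Ccnd1 (log2 fold change -0.55) and Ccnd2 (452 ± 27.1 to 245 ± 14.1 CPM). The set stood above other genes (camera adjusted p = 1.56e-10), lost with an estimated correlation (adjusted p = 0.419).

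Genes of energy metabolism that passed were mostly higher. Of 55 tested nuclear genes of oxidative phosphorylation, 36 rose and 0 fell (40 and 0 when adjusted over the list alone), with a median log2 fold change of 0.29. Uqcr10, a subunit of complex III, rose from 37.4 ± 0.932 to 90.8 ± 0.534 CPM, and the complex I subunits Ndufa10 and Ndufa9 from 67.2 ± 1.17 to 109 ± 10.2 CPM and from 80.3 ± 3.42 to 125 ± 5.76 CPM. Atp5b, the catalytic subunit of ATP synthase, rose from 745 ± 2.35 to 1066 ± 40.5 CPM. The camera adjusted p was 7.70e-08 (adjusted p = 0.419 with an estimated correlation). Of 22 glycolysis genes, 13 rose and 2 fell, the same when adjusted over the list alone (camera adjusted p = 0.00215, and adjusted p = 0.419 with an estimated correlation). The glucose transporter gene Slc2a1 rose from 93.8 ± 3.09 to 245 ± 20.9 CPM, Hk2 from 106 ± 1.00 to 181 ± 7.45 CPM, Pgam1 from 70.6 ± 0.0334 to 119 ± 11.7 CPM and Ldha from 373 ± 14.2 to 552 ± 23.1 CPM.

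Of 26 tested fatty acid oxidation genes, 11 rose and 4 fell (12 and 4 when adjusted over the list alone). Acaa2, a mitochondrial thiolase, rose from 90.3 ± 0.204 to 157 ± 0.511 CPM and Acot2 from 4.31 ± 0.0425 to 13.5 ± 1.59 CPM. Cpt1a, the entry enzyme of the pathway, fell from 140 ± 2.38 to 89.5 ± 2.17 CPM. Cd36, which macrophages also express, fell further (log2 fold change -5.14) than the median of the leukocyte markers (-2.46). A link between these falls was not tested. The set sat at the threshold (camera adjusted p = 0.04997), and its adjusted p was 0.419 with an estimated correlation. It passed under 3 of 18 alternatives (adjusted p from 0.0282 to 0.419).

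Interferon-stimulated genes were mostly lower in shGrhl3 cells. Of 47 tested, 1 rose, 30 fell and 16 did not pass (1 and 34 when adjusted over the list alone), with a median log2 fold change of -0.70. Stat2, a mediator of the interferon response, fell from 221 ± 29.9 to 115 ± 9.71 CPM (log2 fold change -0.95, SE 0.10, adjusted p = 8.89e-08). Helz2 fell from 109 ± 16.8 to 53.6 ± 0.384 CPM, Ifit2 from 142 ± 18.045 to 74.3 ± 9.72 CPM and the RNA sensor gene Ddx58 from 226 ± 31.6 to 118 ± 15.9 CPM. In all 4 genes the shNT libraries differed more from each other, in CPM, than the shGrhl3 libraries did, but their level was also higher. Relative to level the gap was similar for Ifit2, at 154 and 129 CPM in shNT and 81.1 and 67.4 CPM in shGrhl3. The leukocyte marker sum fell in the same libraries (810 ± 181 to 142 ± 22.3 CPM), and a link between these falls was not tested. Within shNT, the library with the higher marker sum had the lower CPM of all 4 interferon genes named here. That pair of libraries cannot decide on a link, and these genes are not independent (estimated list correlation 0.719). For the interferon list the camera adjusted p was 2.56e-07, against an adjusted p of 0.553 with an estimated correlation and 0.132 by fry. Inflammatory cytokine and NF-kB target genes had 5 of 29 tested members higher and 9 lower (6 and 10 when adjusted over the list alone; camera adjusted p = 0.803). Ccl20, a chemokine, rose from 1.13 ± 0.189 to 21.9 ± 0.696 CPM, C3 from 91.5 ± 2.79 to 197 ± 10.3 CPM and Csf1 from 875 ± 29.8 to 1441 ± 15.2 CPM. Ptgs2, the inducible cyclooxygenase, fell from 15.5 ± 0.905 to 4.92 ± 0.684 CPM.

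Markers of macrophages and other leukocytes fell most of all lists by median. Of 15 tested, 13 fell, 1 rose and 1 did not pass, the same when adjusted over the list alone, with a median log2 fold change of -2.46. Ctss, Cd68 (33.7 ± 6.73 to 6.05 ± 0.537 CPM), Mpeg1 (72.9 ± 17.7 to 7.69 ± 0.0534 CPM) and Laptm5 (14.7 ± 3.38 to 2.65 ± 0.196 CPM) had the lowest p-values. Lyz2, lysozyme, was the most abundant by far at 550 ± 135 CPM in shNT and 88.6 ± 18.2 CPM in shGrhl3. The member that rose was Csf1r, the receptor for Csf1, from 7.25 ± 0.0153 to 17.9 ± 1.04 CPM. The camera adjusted p was 1.40e-06 (adjusted p = 0.419 with an estimated correlation).

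**Figure D3:**
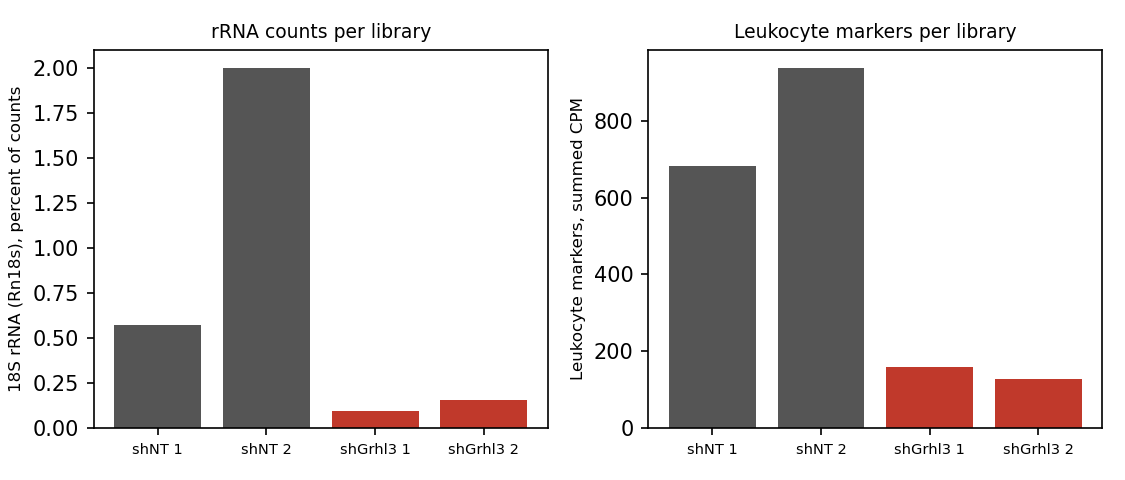
Share of counts in the rRNA gene Rn18s (left, percent of counts) and summed CPM of the leukocyte marker list (right) in each of the 4 libraries, with shNT in grey and shGrhl3 in red and both axes starting at 0. Rn18s takes 0.573% and 2.00% in shNT against 0.0959% and 0.156% in shGrhl3, and the marker sum is 682 and 938 CPM against 158 and 126 CPM. Lyz2 alone makes up 454 and 645 CPM of the sum in shNT, and 102 and 75.7 CPM in shGrhl3.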

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

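The crossed replicate block, the summed rows and the removal of rRNA-related rows were chosen after seeing the data. The count of changed genes, 5402 in the main test, ranged from 3835 (without shNT replicate 1) to 5849 (crossed replicate block) over the fits tried at the same threshold. DESeq2 gave 3896, of which 3868 were shared, and 0 genes were called in the opposite direction in any fit. A minimum log2 fold change of 1 left 1168 genes, 512 higher and 656 lower, by construction. Of the 119 named genes, 109 kept direction and side of the threshold in every refit that tested them, and 0 of their 1903 alternative values changed direction. The fold change minimum and the lower adjusted p threshold were applied to the gene counts only, not to the named genes. Some named genes lie below that minimum, such as Atp5b with a log2 fold change of 0.52. Most named genes were picked by p-value or fold change in these same libraries, so their stability under refits is partly built in. List tests kept both in 413 cases, while 55 lost the threshold, 7 gained it and 11 turned sign.

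With an estimated correlation, a test with few degrees of freedom that no list passed, the sarcomere, fibroblast and leukocyte lists had adjusted p-values of 0.419. Collagens passed by fry (0.0382) and missed the threshold by camera with a library left out (0.0688 to 0.298). Cardiac transcription factors passed by fry (0.0266). Matrix glycoproteins passed with DESeq2 (0.0230) and limma-voom (0.0268) and ranged from 0.0383 to 0.180 with a library left out. The cause was not tested. Lists whose sign turned were far from the threshold on both sides. They were Hippo-YAP targets (fry 0.474), Notch (fry 0.542), inflammatory genes (DESeq2 0.986, limma-voom 0.989, stricter filter 0.839, fry 0.853, leave-one-out 0.437 to 0.901, with turns at 0.755 and 0.901) and Schwann cell markers (fry 0.661, leave-one-out 0.481 to 0.916, with turns at 0.849 and 0.916). The legacy edgeR fit has no list test because its spread estimate does not enter camera.

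With a library left out, the lone library of its group is assumed to vary like the other group. These fits have 1 residual degree of freedom and pooled the spread over nearly all genes, so their p-values carry little of each gene's own spread. The replicate block gave 5042 genes, with adjusted p-values of 0.0174 for Mef2c and 0.0653 for Gata4. Same-numbered libraries did not deviate together (correlation across genes -0.060, and -0.18 among genes with a log2 CPM of at least 4), and nothing in the labels pairs them. Crossing the numbers gave 5849 genes. The log2 fold change of Grhl3 ranged from -1.20 to -0.19, with adjusted p from 0.187 to 0.899. At this depth Grhl2, with 0 to 5 counts per library, was too low to test.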

Other observations

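The tests on library scaling, on rRNA carry-over and on the contractile genes were chosen after the results were seen. Of 23 tested p53 target genes, 13 rose and 1 fell (13 and 2 when adjusted over the list alone; camera adjusted p = 0.0116, and adjusted p = 0.419 with an estimated correlation). Sesn2, a stress-induced regulator of metabolism, rose from 63.2 ± 0.900 to 124 ± 9.14 CPM, Perp from 17.7 ± 0.0506 to 42.4 ± 3.98 CPM and Tnfrsf10b from 113 ± 6.44 to 185 ± 8.48 CPM, while Zmat3 fell from 151 ± 4.87 to 94.9 ± 5.66 CPM. Of 20 unfolded protein response genes, 8 rose and 3 fell (9 and 3 when adjusted over the list alone). Its camera adjusted p of 0.04997 became an adjusted p of 0.50005 with an estimated correlation, and it passed under 4 of 18 alternatives (0.0184 to 0.50005). Chac1 (10.3 ± 0.105 to 36.3 ± 0.613 CPM) and Trib3 (6.33 ± 2.36 to 34.9 ± 0.543 CPM), both induced by the stress factor Atf4, rose, whereas Asns, another target of that factor, fell from 93.1 ± 7.47 to 34.4 ± 1.20 CPM, as did Pdia4 (148 ± 6.88 to 68.4 ± 6.22 CPM). Wnt pathway genes had 6 of 29 higher and 10 lower, the same when adjusted over the list alone (camera adjusted p = 0.268, fry 0.0382). Wnt5b rose from 5.31 ± 0.779 to 32.4 ± 5.28 CPM, and the receptor genes Fzd4 (28.1 ± 0.953 to 13.7 ± 0.409 CPM) and Fzd7 (153 ± 3.05 to 99.0 ± 2.24 CPM) and the antagonist Frzb (55.5 ± 7.13 to 28.1 ± 0.164 CPM) fell. Notch pathway genes had 2 of 14 higher and 2 lower, the same when adjusted over the list alone (camera adjusted p = 0.796): Heyl fell from 13.2 ± 1.17 to 4.06 ± 0.313 CPM and Rbpj from 65.4 ± 2.39 to 41.1 ± 2.21 CPM, and Rfng rose from 8.09 ± 0.943 to 18.7 ± 0.422 CPM. The Notch3 call (77.3 ± 3.02 to 104 ± 25.9 CPM, log2 fold change 0.43, adjusted p = 0.0372) was lost without shGrhl3 replicate 2 (0.233) and with no expression filter (0.0980). Its log2 fold change was 0.17 without shGrhl3 replicate 2 and 0.66 without shGrhl3 replicate 1.

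Markers of other cell types changed less than those of leukocytes. Of 20 endothelial markers, 1 rose and 4 fell, the same when adjusted over the list alone (median -0.35; camera adjusted p = 0.0285, and adjusted p = 0.419 with an estimated correlation). Flt1 rose from 49.8 ± 3.51 to 68.8 ± 4.39 CPM, Eng fell from 402 ± 21.5 to 329 ± 25.05 CPM, and Tek (11.3 ± 1.05 to 7.67 ± 1.08 CPM) and Cldn5 (1.93 ± 1.18 to 0.505 ± 0.573 CPM) fell at low counts. The Eng call was lost without shNT replicate 2 (adjusted p = 0.177), and the Tek call with DESeq2 (0.124) and without shNT replicate 1 (0.167) or shGrhl3 replicate 2 (0.157). The Cldn5 call was lost under 5 of 16 alternatives, among them DESeq2 (0.0991), no filter (0.0527) and the fits without shNT replicate 2 (0.273) or shGrhl3 replicate 1 (0.172). Its log2 fold change of -1.91 became -1.15 and -1.03 in those fits, and -4.11 without shGrhl3 replicate 2. The set missed the threshold with DESeq2 (0.111), limma-voom (0.101), the stricter filter (0.0596) and without shNT replicate 1 (0.0660) or shGrhl3 replicate 1 (0.0844). Of 17 smooth muscle and pericyte markers, 3 rose and 2 fell (camera adjusted p = 0.719), with Cspg4 (55.2 ± 6.80 to 98.6 ± 3.66 CPM) and Des (745 ± 26.1 to 1140 ± 36.4 CPM) higher and Tagln (412 ± 3.28 to 290 ± 7.84 CPM) lower. The other falling call, Cnn1 (7.19 ± 0.104 to 4.55 ± 0.228 CPM), was lost with DESeq2 (adjusted p = 0.138) and without any 1 of the libraries (0.0540 to 0.104). Of 16 mesothelial and epicardial markers, 4 rose and 2 fell (camera adjusted p = 0.268, fry 0.0147). Upk3b, a mesothelial surface gene, rose from 41.0 ± 3.45 to 101 ± 6.82 CPM, and Aldh1a2, which makes retinoic acid, fell from 51.6 ± 8.77 to 29.95 ± 1.93 CPM. Of 8 Schwann cell and neural markers, Mbp rose (3.50 ± 2.00 to 11.4 ± 1.63 CPM), Tubb3 fell (56.6 ± 3.33 to 37.6 ± 0.604 CPM) and the others did not pass (camera adjusted p = 0.807). The log2 fold change of Mbp, 1.74 in the main fit, ranged from 1.21 to 2.44 over the alternatives. For the smooth muscle, mesothelial and Schwann cell lists the counts were the same when adjusted over the list alone. Of 10 erythroid markers, 9 were found among the counted genes and 0 were expressed highly enough to test.

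The fall of leukocyte markers is the pattern with the largest list median. A further list of leukocyte genes, sharing no gene with the fixed lists and written before it was tested, had a median log2 fold change of -2.08 over 38 tested genes, with 27 lower and 1 higher. The lowest median of 10000 random lists matched on mean expression was -0.82, against -2.46 for the marker list. A scaling shift common to all genes, or abundance alone, would have moved those lists as well. The marker list was singled out for its median and random members were drawn independently, so the comparison gives no measure of chance. Fewer leukocytes among the shGrhl3 cells, whether through the hairpin or through the starting cultures, is a candidate explanation, in line with the further list, and so is a lower expression of these genes within the leukocytes present; the counts hold no value that separates them. Csf1r (7.25 to 17.9 CPM) and Ncf4 (16.2 to 22.2 CPM) rose against the trend, and the 4 genes of the further list at 10 CPM or more in shGrhl3, which other cells may express, were Ncf4, Ctsd (1460 and 1411 CPM), Lgals3 (78.1 and 86.2 CPM) and Gpnmb, which fell from 1026 to 493 CPM.

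The Rn18s share, whose group difference did not pass the test, differed 3.49-fold between the 2 shNT libraries. The 46 ribosome biogenesis genes had a median log2 fold change of 0.08, with 7 higher and 4 lower. A lower median, predicted in advance for a change in ribosome production, was thus not seen. These mRNA levels do not measure rRNA synthesis, so they cannot decide whether ribosome production changed. Differing rRNA carry-over between libraries stays open: the share varied within shNT, but both shGrhl3 shares lay below both shNT shares, and 2 libraries per group do not separate carry-over from an effect of the hairpin. Lars2, whose locus carries an rRNA-like repeat, took 0.219 ± 0.0773% of counts in shNT and 0.0231 ± 0.0136% in shGrhl3 (SD, n = 2), a difference that did not pass the test (log2 fold change -3.27, adjusted p = 0.0941). Whether mRNA changes follow the rRNA content stays open: a correlation over the changed genes was computed and left out, since those genes were chosen for the group difference and the shNT libraries entered both sides.

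The rise of contractile genes came without a uniform cardiomyocyte shift. A larger share of reprogrammed cells alone would raise genes that only those cells express. Of 52 sarcomere and calcium handling genes, 25 rose and 6 fell past the threshold, and Tnnt2 did not pass. Among the falling genes were Myl4, Tcap, Pdlim5, Kcnj5 and Hcn4. These counts were known when the test was chosen, and which cells express these genes was not measured. The test therefore does not set a larger share aside. A move of counted reads between Myh6 and Myh7 is argued against, since the summed counts of both rose by 3.58 on the log2 scale (SE 0.10). Reads that fit both genes, if dropped in counting, are not in that sum, which cannot speak to them. Myh7 is a small part of that sum, with 11 and 14 counts in shNT and 89 and 92 in shGrhl3. Myh7 rose as well (log2 fold change 2.70, SE 0.38, adjusted p = 6.19e-06 in the edgeR test). Also open for the contractile genes are a changed type or maturity of the induced cells and a hairpin side effect unrelated to Grhl3. A single hairpin label is present, its sequence was not used here and a fall of Grhl3 was not detected.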
